A study of Mus musculus with 6 samples.

How the data were processed

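Mouse embryonic stem cell (ESC) cultures of the strain 129X1/SvJ x 129S1/Sv were sorted by flow cytometry on the surface proteins PECAM1, an adhesion molecule carried by undifferentiated ESCs, and PDGFRa, a receptor for platelet-derived growth factor. Total RNA of 3 fractions was sequenced on an Illumina instrument after amplification. The labels give 100000 sorted events and passages 13 to 17 for every library. The fractions are called here PDGFRa-only (PECAM1minPDGFRaplus in the labels), PECAM1-only (PECAM1plusPDGFRamin) and double-positive (PECAM1plusPDGFRaplus), with 2 libraries each and 6 libraries in all. The labels number the libraries of each fraction Exp1 and Exp2, called replicates 1 and 2 here. They do not say whether the numbers stand for separate cultures or whether same-numbered libraries come from the same sort. Each p therefore measures the spread between these libraries alone.

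The deposited count table holds raw counts per Ensembl gene, with no normalization. The authors' processing notes list cutadapt 1.2.1, Bowtie2 2.1.0, TopHat2 2.0.8b and HTSeq 0.5.4p3 and the mouse genome build GRCm38, without the role or order of each tool. A further deposited table gives RPKM values, preprocessed by the authors in a way that is not stated. It lists 16105 genes, none with a value of 0, and its values are not the counts divided by transcript length and library size: 6 genes had an identical value in all 6 libraries (tolerance 0), and the log2 fold changes between the PDGFRa-only and PECAM1-only fractions from RPKM and from counts correlated across genes with r = 0.848, with 2123 genes more than 1 log2 unit apart. Rpl4 is an example chosen after its values were seen: its RPKM was 11.7-fold higher in the PECAM1-only fraction, while its counts gave a log2 fold change of -0.24 (adjusted p = 0.215, edgeR). All tests therefore used the counts, and RPKM served only as an alternative.

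The count table held 38561 genes, of which 24748 had at least 1 count. Gene symbols, positions and types came from GENCODE M21, to which 36639 of the identifiers matched; the annotation release used by the authors is not stated. Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were also used). Genes were kept by filterByExpr with a minimum count of 10, which left 13909. Library sizes were scaled by TMM (the trimmed mean of M-values), and a quasi-likelihood model with 1 mean per fraction was fitted robustly to all 6 libraries, with 3 residual degrees of freedom. Tests were two-sided. P values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05. Levels are normalised read counts relative to library size (CPM, as edgeR computes them), given as the mean ± SD of 2 libraries. The biological coefficient of variation was 13.5%. In each comparison a positive log2 fold change means a higher level in the fraction named before the other.

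Where all libraries of a fraction had 0 counts, the fold is a lower bound against a floor of 3 counts over that fraction. Where it had 1 to 3 counts, the ratio is given with its exact 95% counting interval. Amplified reads without molecular identifiers are not independent molecules, so these floors and intervals cover counting error only.

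Gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The rule named Pecam1 and Pdgfra, up to 8 genes with the largest rise and 8 with the largest fall in each comparison (mean of at least 5 CPM over the 6 libraries and the same direction in both library numbers), and the 4 members of each list with the smallest p; values of part of them are given. Rank followed the fitted fold change, which for a gene with 0 counts in a fraction is no bound, so the order of such genes is not exact. The 28 lists were primitive endoderm regulators and receptors, basement membrane, visceral endoderm, parietal endoderm, definitive and anterior endoderm, naive pluripotency, general pluripotency, post-implantation epiblast, gastrulation mesoderm, neural, trophoblast, 2-cell-like, mesenchymal (fibroblast), endothelial and blood, FGF and ERK targets, FGF and PDGF ligands and receptors, LIF and STAT3 signalling, BMP, Nodal and TGF-beta targets, Wnt targets, epithelial junctions, cell cycle, p53 targets, dissociation stress, glycolysis, imprinted genes, DNA methylation enzymes, mitochondrially encoded and ribosomal proteins. The 26 lists with at least 3 tested members were tested with camera (limma) at a preset correlation of 0.01, which compares the members of a list with all other tested genes, and adjusted over those 26. Camera with an estimated correlation, and fry, which asks whether the members move on balance in 1 direction without comparing them with other genes, were run beside it. With an estimated correlation camera refers its statistic to the 3 residual degrees of freedom, and with the preset to far more. This alone raises its p.

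Alternatives were RLE, upper-quartile and library-size scaling, no filter and a stricter filter (minimum count 50), DESeq2, limma-voom, limma on log2(RPKM + 1) and log2(RPKM + 0.1), an adjusted p of 0.01, an absolute log2 fold change of at least 1, the library number as a block, the 2 compared fractions alone, and leaving out each library. A correction of each library for its trend with transcript length and GC content, that correction with the block, and leaving out ribosomal RNA-like genes were added after seeing the data. The pipeline was tested on simulated data with the depth and spread of these libraries: of 100 genes changed 2-fold, 77%, 76% and 75% were recovered in the 3 comparisons, of 100 changed 4-fold, 99%, 100% and 98%, and 4, 13 and 8 unchanged genes were called. The changed genes in these simulations had a mean of at least 5 CPM and went up and down in equal numbers. In the data 17.6% to 59.0% of tested genes passed, so the simulated rates do not cover lower genes or changes this widespread. No library was left out of the main comparisons.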

Results

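RNA sequencing measured gene expression in 3 fractions of undifferentiated mouse ESC cultures, sorted by the surface proteins PECAM1 and PDGFRa. The series title presents PDGFRa-positive cells of ESC cultures as an in vitro counterpart of the precursors of primitive endoderm, the tissue that forms beside the pluripotent epiblast before implantation, and the comparisons address how the fractions differ in genes of these tissues. Each fraction had 2 libraries. The libraries held 4809661 and 7273669 counts in the PDGFRa-only fraction, 6147345 and 5694077 in the PECAM1-only fraction, and 6568777 and 6634022 in the double-positive fraction. Counts were found for 17811 and 18785 genes, 20509 and 20510 genes, and 19958 and 20364 genes, in the same order. On the log2 CPM scale, the first principal component held 83.9% of the variance and ordered the fractions from PDGFRa-only through double-positive to PECAM1-only. Replicates correlated across genes with r = 0.977, 0.984 and 0.984, against 0.718 to 0.738 between PDGFRa-only and PECAM1-only libraries; genes are not independent replicates. The mitochondrial ribosomal RNA mt-Rnr2 took 12.8% to 17.9% of the counts of each library. The transcript RP23-81C12.3 took 7.71% in PDGFRa-only replicate 1 and 1.52% to 2.87% in the other 5 libraries.

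The genes of both sorting proteins followed the labels. Pecam1 (ENSMUSG00000020717, GRCm38 chromosome 11, 106654217 to 106750628) had 1.54 ± 0.0430 CPM in the PDGFRa-only fraction, 49.4 ± 6.30 CPM in the double-positive and 154 ± 16.3 CPM in the PECAM1-only fraction (SD, n = 2). Pdgfra (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215) had 557 ± 68.2 CPM, 535 ± 24.1 CPM and 1.96 ± 0.111 CPM, in the same order. The double-positive fraction therefore carried 32.0% (SD 4.08) of the Pecam1 level of the PECAM1-only fraction and 96.0% (SD 4.33) of the Pdgfra level of the PDGFRa-only fraction. Pecam1 differed in all 3 comparisons, with adjusted p of 2.34e-14 between the single-positive fractions, 1.55e-07 between double-positive and PECAM1-only, and 1.12e-10 between PDGFRa-only and double-positive. Pdgfra differed from the PECAM1-only fraction in both others (adjusted p = 3.62e-16 and 8.07e-16) and had a log2 fold change of 0.06 between PDGFRa-only and double-positive (adjusted p = 0.834).

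**Figure D1:**
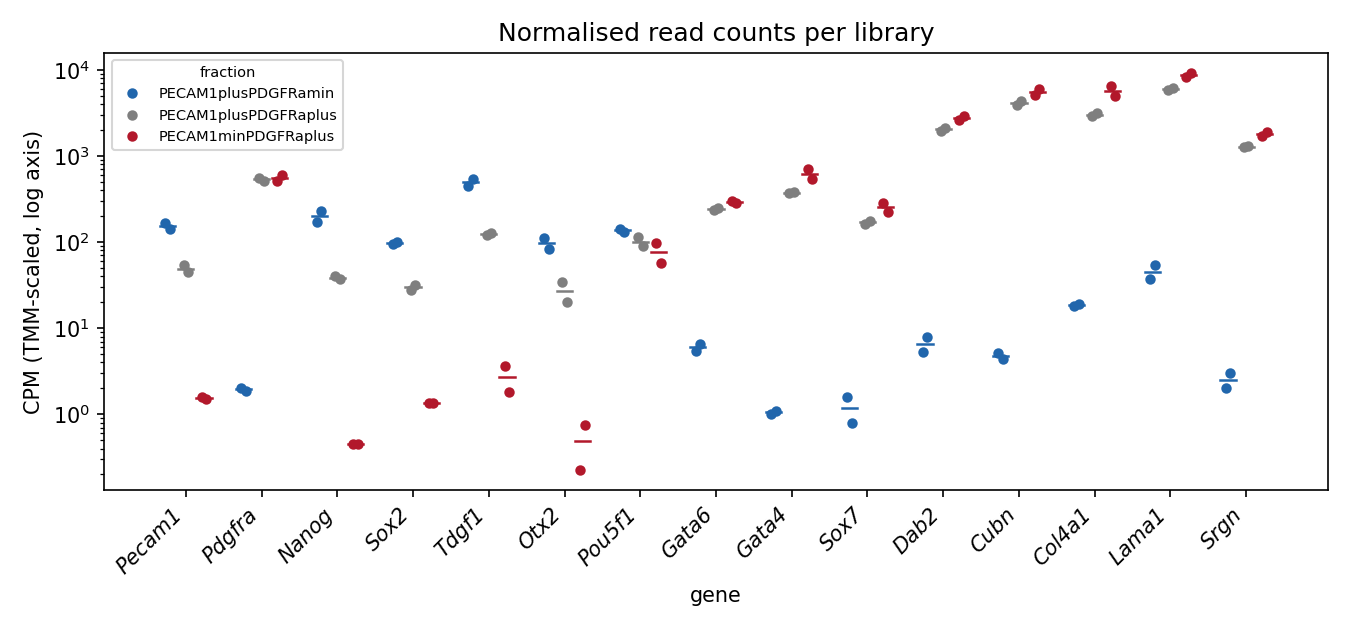
Normalised CPM of 15 genes on a log axis; each dot is a library (2 per fraction) and each line the mean of a fraction. Cubn, Dab2 and Gata4 lie high in both PDGFRa-positive fractions, Nanog and Tdgf1 are highest in the PECAM1-only fraction and lowest in the PDGFRa-only fraction, and Pecam1 lies between the others in the double-positive fraction.

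The first comparison asked how PDGFRa-only cells differ from PECAM1-only cells. Transcripts of primitive endoderm were abundant in the PDGFRa-only fraction and nearly absent from the PECAM1-only fraction. Cubn, an endocytic receptor, had 5594 ± 683 CPM against 4.74 ± 0.498 CPM, and the endoderm transcription factor Gata4 had 623 ± 106 CPM against 1.06 ± 0.0556 CPM (SD, n = 2). The pluripotency genes Nanog and Sox2 went the other way: Nanog, a transcription factor of the naive state, had 0.451 ± 0.00297 CPM against 199 ± 41.4 CPM, and Sox2 had 1.35 ± 0.00892 CPM against 97.0 ± 3.71 CPM. The low levels of both rest on few reads, so their SD understates the counting error. Of 13909 tested genes, 4193 were higher and 4012 lower in the PDGFRa-only fraction, 59.0% in all, and 5650 of them differed at least 2-fold.

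All 15 primitive endoderm regulators and receptors rose. Their median log2 fold change was 7.97, or 7.70 with genes at their floor (camera adjusted p = 4.76e-39, adjusted p = 0.0518 with an estimated correlation). They included Cubn (log2 fold change 10.20), the endocytic adaptor Dab2 (8.71) and Gata4 (9.17). Of 17 basement membrane genes, 13 rose and 4 fell. Their median was 3.59 (adjusted p = 6.72e-18, adjusted p = 0.131 with an estimated correlation). The collagen IV chain gene Col4a1 had 5725 ± 1062 CPM against 18.6 ± 0.763 CPM, and the laminin chain gene Lama1 had 8811 ± 632 CPM against 45.2 ± 11.9 CPM. The 4 that fell, named after their values were seen, were Lama5 (-2.47), Fn1 (-2.46), Agrn (-0.43) and Col18a1 (-5.27), which also encode matrix proteins. Agrn was lost without PDGFRa-only replicate 1 (adjusted p = 0.212), PECAM1-only replicate 2 (0.239) and double-positive replicates 1 (0.0544) and 2 (0.0528). Of 13 visceral endoderm genes, 7 were tested. Too low to be tested were Afp (14 counts over all 6 libraries), Apoa1 (7), Apoa2 (5), Apoa4 (15), Apoc2 (4) and Trf (3). Of the 7 genes tested, 6 rose. Their median was 2.36 (adjusted p = 0.000112, adjusted p = 0.131 with an estimated correlation). Among them were the trypsin inhibitor gene Spink3 (6.84) and the nuclear receptor gene Hnf4a (2.36). Ttr, a thyroid hormone carrier, had 13.0 ± 4.75 CPM against 0 counts, at least 57.5-fold higher. Of 10 parietal endoderm genes, 9 rose and 1 fell. Their median was 6.18 (adjusted p = 9.77e-16, adjusted p = 0.0701 with an estimated correlation). Srgn, a proteoglycan gene, had 1810 ± 148 CPM against 2.51 ± 0.666 CPM, and the member that fell was Vim, which encodes the filament protein vimentin (-2.35). Among 4 definitive and anterior endoderm genes tested, 2 rose and 1 fell, with no camera call for the list (adjusted p = 0.364) and an upward call by fry (adjusted p = 0.00811). The Wnt inhibitor gene Dkk1 and Hhex (1.00) rose, Dkk1 to 31.9 ± 1.27 CPM against 1 count in replicate 2 of the PECAM1-only fraction, a ratio of 425 (counting interval 75.7 to 1.68e+04). The member that fell was Lefty1, an inhibitor of Nodal, with a log2 fold change of -3.03, which was -2.26 without replicate 1 and -7.99 without replicate 2 of the PDGFRa-only fraction.

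Among 19 naive pluripotency genes, 13 fell, 4 rose and 2 did not pass. Their median was -2.50 (adjusted p = 7.70e-07, adjusted p = 0.242 with an estimated correlation). Prdm14 had 0.451 CPM against 27.2 ± 1.02 CPM, a log2 fold change of -5.85. The 4 that rose, named after their values were seen, were Klf5 (0.90), Tbx3 (1.60), Dppa5a (0.66) and Tdh (1.74); the call of Klf5 was lost without PDGFRa-only replicate 1 (0.38, adjusted p = 0.0539) and that of Dppa5a without PECAM1-only replicate 1 (adjusted p = 0.0582) and with library-size scaling (0.0604). Klf5 and Tbx3 encode transcription factors and Tdh a threonine dehydrogenase. Of 12 general pluripotency genes, 10 fell and none rose. Their median was -1.71 (adjusted p = 1.27e-07, adjusted p = 0.242 with an estimated correlation). Tdgf1, a co-receptor for Nodal, had 2.70 ± 1.26 CPM against 494 ± 59.9 CPM. The post-implantation epiblast list fell in 9 of 11 genes and rose in 1. Their median was -1.81 (adjusted p = 0.000148, adjusted p = 0.266 with an estimated correlation), with Lef1 at -6.76 and Zic2 at -5.10, while the DNA methyltransferase gene Dnmt3b, named after its value was seen, rose (0.52). Dnmt3b was lost without PDGFRa-only replicates 1 (adjusted p = 0.0623) and 2 (0.0508) and PECAM1-only replicate 2 (0.320), with upper-quartile (0.142) and library-size scaling (0.282) and with DESeq2 (0.0507). All 6 neural genes tested fell. Their median was -2.72 (adjusted p = 0.00525, adjusted p = 0.242 with an estimated correlation), with Tubb3 at -2.56 and Pax6 at -3.91. Of 18 cell cycle genes, 14 fell and none rose. Their median was -0.68 (adjusted p = 0.00697, adjusted p = 0.242 with an estimated correlation). The replication helicase gene Mcm6 had 102 ± 2.05 CPM against 285 ± 11.7 CPM, and Top2a had 715 ± 126 CPM against 1783 ± 22.8 CPM. Of 12 p53 targets, 9 fell and 2 rose. Their median was -0.77 (adjusted p = 0.0251, adjusted p = 0.242 with an estimated correlation), with Perp at -5.22 and Trp53inp1 at -2.32. The 2 that rose, named after their values were seen, were Ccng1 (0.68) and Phlda3 (0.49), the latter lost without PDGFRa-only replicate 1 (adjusted p = 0.0753) and PECAM1-only replicates 1 (0.0825) and 2 (0.138), with upper-quartile (0.199) and library-size scaling (0.363), with the stricter filter (0.0508) and with DESeq2 (0.114). Of 8 DNA methylation enzyme genes, 5 fell and 1 rose. Their median was -0.85 (adjusted p = 0.0481, adjusted p = 0.557 with an estimated correlation). Tet1 had 320 ± 7.58 CPM against 2435 ± 184 CPM, and Dnmt3b was the member that rose. This last list call was lost in several settings, with adjusted p of 0.0712 without PDGFRa-only replicate 2, 0.0863 without PECAM1-only replicate 1, 0.0608 and 0.0598 without double-positive replicates 1 and 2, 0.0533 without a count filter and 0.0651 in a fit of these 2 fractions alone.

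The endothelial and blood list marks other cell types that carry PECAM1. Members too low to be tested were Ptprc, Erg and Emcn (0 counts over all 6 libraries), Tie1 (2), Sox18 (10), Gata1 (11) and Tal1 (21). Of the 7 genes tested, 4 rose and 1 fell. Their median was 4.32 (adjusted p = 0.000148, adjusted p = 0.131 with an estimated correlation, adjusted p = 0.357 and median 0 without a count filter). Flt1, a receptor for vascular endothelial growth factor, had 182 ± 5.55 CPM against 1.80 ± 0.332 CPM, the transcription factor gene Runx1 had 175 ± 46.1 CPM against 0.756 CPM, and Kdr rose by 4.32. Cdh5 rose by 9.85, which was 8.98 without PECAM1-only replicate 1 and 12.08 without replicate 2. Eng, named after its value was seen, fell (-0.82), a call that did not hold without PDGFRa-only replicate 2. The trophoblast list split, with 4 genes up, among them the keratin genes Krt8 (7.76) and Krt18 (6.36), and 4 down (camera adjusted p = 0.129, or 0.00980 with the stricter filter, and 0.0184 upwards by fry). The others, named after their values were seen, were Tead4 and Plac1 upwards and Ascl2, Tfap2a, Tfap2c and Cldn4 downwards. Trophoblast genes too low to be tested were Cdx2 (7 counts over all 6 libraries), Elf5 (8), Gata3 (27), Gata2 (5), Krt7 (11), Hand1 (36) and Dlx3 (9). Mesenchymal (fibroblast) genes numbered 8, of which 2 rose, 1 fell and 5 did not pass (adjusted p = 0.982). The 2 that rose were Col1a2, at 3.02 ± 2.36 CPM and a ratio of 22.1 (counting interval 5.71 to 190) to 2 counts in the PECAM1-only fraction, both in replicate 1, and Tagln, whose log2 fold change of 1.95 was 1.27 (adjusted p = 0.166) without PDGFRa-only replicate 2 and no longer passed (adjusted p = 0.0753) without PECAM1-only replicate 1. The member that fell, Loxl1, had 1 count in the PDGFRa-only fraction, in replicate 1, and was lower by a ratio of 22.6 (3.72 to 924). Of the gastrulation mesoderm list only Eomes was tested, with a log2 fold change of -0.64 (adjusted p = 0.103), which passed with upper-quartile (adjusted p = 0.0345) and library-size scaling (adjusted p = 0.0202) and without PDGFRa-only replicate 1 (adjusted p = 0.0148). None of the 2-cell-like genes was tested.

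The remaining lists, on signalling, junctions, stress, metabolism, imprinting and housekeeping, had no camera call. Of 14 FGF and ERK targets, 8 fell and 3 rose (adjusted p = 0.512, with a downward call by fry, adjusted p = 0.0291): Etv5 had 16.4 ± 2.23 CPM against 176 ± 14.3 CPM, while Dusp4, a phosphatase that acts on ERK, rose by 3.85. Among 11 FGF and PDGF ligands and receptors, 5 rose and 5 fell (adjusted p = 0.942), with Fgfr2 at 106 ± 10.1 CPM against 15.1 ± 3.37 CPM and Fgfr1 at 5.04 ± 1.42 CPM against 112 ± 9.01 CPM. Of 13 LIF and STAT3 signalling genes, 7 rose, among them the LIF receptor gene Lifr (1.97), and 4 fell, among them Tfcp2l1 (-1.40; adjusted p for the list = 0.676). Of 13 BMP, Nodal and TGF-beta targets, 3 rose and 6 fell (adjusted p = 0.826), with Pmepa1 at 3.33 and Nodal at -4.81. Of 8 Wnt targets, 4 rose and 3 fell (adjusted p = 0.676), with Tcf7 at -2.64. Of 13 epithelial junction genes, 5 rose and 5 fell (adjusted p = 0.982), with Jup at 1.58 and Pkp2 at -3.86. Of 14 dissociation stress genes, 8 rose, among them Atf3 (4.84) and Jun (2.93), and 5 fell (adjusted p = 0.364). Of 14 glycolysis genes, 3 rose and 4 fell (adjusted p = 0.422), with Pfkp at -2.18 and Pfkl at 1.27. Of 12 imprinted genes, 5 rose and 6 fell (adjusted p = 0.621), with Mest at 12.6 ± 5.08 CPM against 195 ± 11.9 CPM and Peg3 at 1041 ± 292 CPM against 226 ± 36.9 CPM. Of 6 mitochondrially encoded genes 3 passed (adjusted p for the list = 0.512), namely mt-Nd1 (0.64), mt-Nd4 (0.69) and mt-Nd5 (0.58). Each was lost without PECAM1-only replicate 1, at log2 fold changes of 0.34, 0.38 and 0.25. In the same order, each was also lost with upper-quartile (adjusted p = 0.0567, 0.0777 and 0.117) and library-size scaling (0.119, 0.135 and 0.222). DESeq2 did not call mt-Nd4 either (0.177). Of 20 ribosomal protein genes, 1 rose and 3 fell (adjusted p = 0.473), with Rpl3 at -0.95 and Rpl30 at -0.80. Rplp0 (0.54) was lost without PDGFRa-only replicate 1 (adjusted p = 0.412) and PECAM1-only replicate 1 (0.196), with upper-quartile (0.149) and library-size scaling (0.277) and with DESeq2 (0.0591), and Rpl5 (-0.65) without the same libraries (0.0583 and 0.205). Adjusted over the list alone, the counts were the same for all 26 lists except epithelial junctions (5 up, 6 down) and ribosomal proteins (0 up, 2 down). Median and mean differed in sign for trophoblast (-0.13 and 0.30, with a median of 0.17 with genes at their floor) and FGF and PDGF ligands and receptors (0.86 and -0.81), and the test pointed down against positive medians for mesenchymal genes (0.14) and Wnt targets (0.26); with library-size scaling these last 2 medians were -0.15 and -0.03.

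The largest fitted rises among genes of at least 5 CPM included those of Habp2, a plasma protease gene (chromosome 19, 56287137 to 56320822), at 87.3 ± 10.1 CPM against 0 counts, at least 385-fold, and of Cdh6 (at least 219-fold), Lgals2 (at least 198-fold), Lpar3 (at least 173-fold), Foxa2, an endoderm transcription factor gene (at least 157-fold), Frzb (at least 136-fold) and Gm4980 (at least 130-fold). Dram1 had 139.9 ± 6.40 CPM against 1 count, in replicate 1 of the PECAM1-only fraction, a ratio of 1865 (counting interval 334 to 7.37e+04). The largest fitted falls included those of Nphs1, a gene of the kidney filtration barrier (chromosome 7, 30458315 to 30487223), at 0 counts against 46.2 ± 1.58 CPM, at least 171-fold lower, and of Prmt8 (at least 119-fold), Slc27a2 (at least 102-fold), Pla2g1b (at least 76.8-fold), Nlrp14 (at least 71.2-fold) and 2900026A02Rik (at least 60.8-fold). Fgf4, an ESC growth factor gene (chromosome 7, 144847367 to 144865243), had 118 ± 23.3 CPM in the PECAM1-only fraction and 1 count, in replicate 1, in the PDGFRa-only fraction, a ratio of 1301 (233 to 5.14e+04). Cobl had 165 ± 32.1 CPM against 1 count, in replicate 2, a ratio of 1822 (327 to 7.20e+04).

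By camera, 12 of 26 lists passed, 5 up and 7 down. With an estimated correlation 0 passed (limma), with 5 at an unadjusted p below 0.05, and fry passed 15. A correlation above the preset 0.01 does not account for all the lost calls. For visceral endoderm, endothelial and blood, and p53 targets the estimates were lower, at -0.000505, -0.0722 and -0.0209. Their unadjusted camera p still rose from 2.58e-05, 4.56e-05 and 0.0106 to 0.0227, 0.0246 and 0.0743. The other lists that passed had estimates above the preset. The version with an estimated correlation also rests on 3 residual degrees of freedom. Its larger p therefore do not measure the correlation of the members alone. The balance of rises and falls depended on the scaling: 51.1% of calls were higher with TMM, 49.2% with RLE, 41.5% with upper-quartile and 37.8% with library-size scaling, which moved the median of all genes by -0.20 and -0.29 for the last 2.

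**Figure D2:**
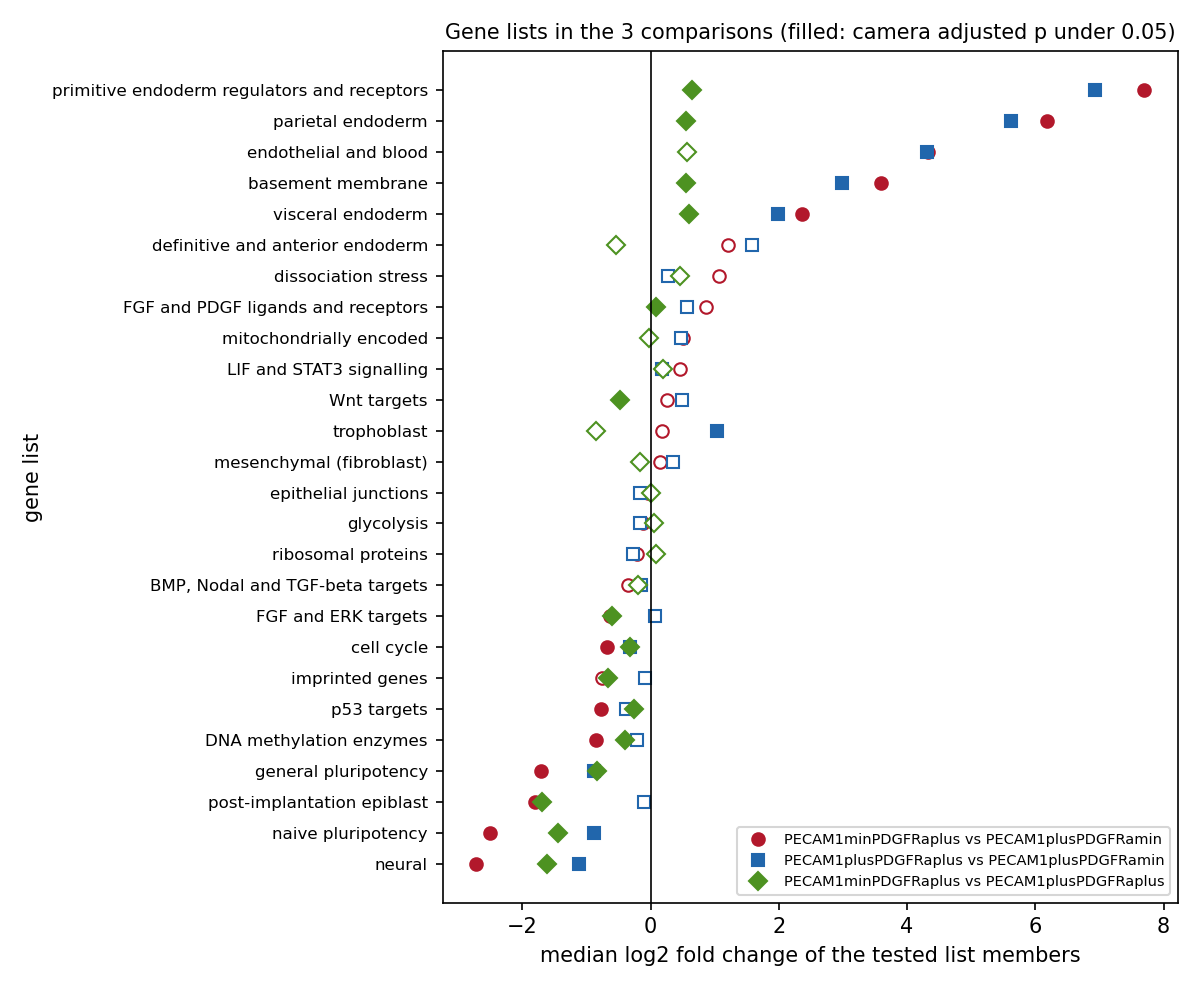
Median log2 fold change of the members of each of the 26 tested lists in the 3 comparisons, with genes at 0 counts in a fraction set to their floor; filled symbols have a camera adjusted p below 0.05. The primitive endoderm list lies at 7.70 between the PDGFRa-only and PECAM1-only fractions.

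The next comparison asked how double-positive cells differ from PECAM1-only cells. The primitive endoderm genes Cubn and Gata6 were higher in the double-positive fraction, and the pluripotency genes Nanog and Fgf4 were detected there at lower levels than in the PECAM1-only fraction. Cubn had 4098 ± 292 CPM against 4.74 ± 0.498 CPM, and Gata6, a transcription factor of primitive endoderm (chromosome 18, 11052064 to 11085635), had 243 ± 7.79 CPM against 5.99 ± 0.848 CPM (SD, n = 2). Nanog (chromosome 6, 122707489 to 122714633) had 38.6 ± 2.37 CPM against 199 ± 41.4 CPM, and Fgf4 had 26.1 ± 2.89 CPM against 118 ± 23.3 CPM. In all, 3031 genes were higher and 2288 lower, 38.2% of those tested, and 3220 differed at least 2-fold.

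All 15 primitive endoderm regulators and receptors rose again (median 7.11, or 6.93 with genes at their floor; adjusted p = 1.62e-62), and this list passed with an estimated correlation as well (adjusted p = 0.0363). So did the parietal endoderm list, where 9 of 10 genes rose and 1 fell. Their median was 5.63 (adjusted p = 1.16e-27, adjusted p = 0.0489 with an estimated correlation); Srgn had 1284 ± 16.3 CPM against 2.51 ± 0.666 CPM. Of 17 basement membrane genes, 13 rose and 3 fell. Their median was 2.99 (adjusted p = 7.31e-33, adjusted p = 0.0883 with an estimated correlation), with Col4a1 at 3022 ± 177 CPM and Lama1 at 5996 ± 186 CPM. Members that fell, named after their values were seen, were Col18a1 (-1.15), Fn1 (-1.27) and Lama5 (-0.59), and Vim (-0.48) in the parietal list. Lama5 was lost without PECAM1-only replicate 2 (adjusted p = 0.150) and double-positive replicate 1 (0.197), and Vim without either PECAM1-only (0.104 and 0.0651) or double-positive library (0.148 and 0.103). All 7 visceral endoderm genes tested rose. Their median was 1.98 (adjusted p = 2.78e-05, adjusted p = 0.128 with an estimated correlation), with Hnf4a at 1.98. Ttr had 7.53 ± 0.0301 CPM against 0 counts, at least 33.3-fold higher. The endothelial and blood list rose in 4 of 7 genes and fell in 1. Their median was 4.32 (adjusted p = 2.47e-06, adjusted p = 0.0883 with an estimated correlation, adjusted p = 0.245 and median -0.22 without a count filter), with Flt1 at 121 ± 18.2 CPM and Runx1 at 116 ± 17.7 CPM. Cdh5 rose by 9.15, which was 8.28 without PECAM1-only replicate 1 and 11.39 without replicate 2. Eng, named after its value was seen, fell by 0.70, a call lost without either PECAM1-only (adjusted p = 0.0870 and 0.117) or double-positive library (0.0975 and 0.139). The trophoblast list rose in 4 of 8 genes and fell in 2. Their median was 1.04 (adjusted p = 0.0110, adjusted p = 0.266 with an estimated correlation), with Krt8 at 6.92, Krt18 at 5.37 and Tead4 at 2.58. The 2 that fell, named after their values were seen, were Tfap2c (-1.70) and Cldn4 (-1.89), the latter at -1.19 (adjusted p = 0.210) without PECAM1-only replicate 2, -1.39 (0.0908) without double-positive replicate 1 and -2.60 without double-positive replicate 2. The call of the list was lost when any of the 6 libraries was left out. The median was then negative in 4 of these 6 and was -0.96 without double-positive replicate 2. It was -0.33 and -0.34 without PDGFRa-only replicates 1 and 2, although these libraries are not among those compared. Leaving out a library also loosened the count filter and could add low-count members. The losses therefore do not show dependence on single libraries. The call was also lost without a count filter (adjusted p = 0.555, median -0.14) and with the library number as a block (0.0544).

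Of 19 naive pluripotency genes, 12 fell and 3 rose. Their median was -0.88 (adjusted p = 9.63e-05, adjusted p = 0.266 with an estimated correlation), with Prdm14 at -2.21 and Zfp42 at -1.69. The 3 that rose, named after their values were seen, were Tbx3 (1.40), Tdh (1.00) and Klf5 (0.71), the last lost without PECAM1-only replicates 1 (adjusted p = 0.103) and 2 (0.104) and double-positive replicate 1 (0.121) and with upper-quartile (0.0743) and library-size scaling (0.0982). Of 12 general pluripotency genes, 8 fell and none rose. Their median was -0.88 (adjusted p = 0.000165, adjusted p = 0.266 with an estimated correlation). Tdgf1 had 124 ± 3.83 CPM against 494 ± 59.9 CPM, and Sox2 had 29.9 ± 2.43 CPM against 97.0 ± 3.71 CPM. Of 6 neural genes, 4 fell and none rose. Their median was -1.11 (adjusted p = 0.0273, adjusted p = 0.266 with an estimated correlation), with Tubb3 at -1.39. Of 18 cell cycle genes, 8 fell and none rose. Their median was -0.31 (adjusted p = 0.0270, adjusted p = 0.266 with an estimated correlation), with Mcm6 at -0.95 and Mcm2 at -0.94. The post-implantation epiblast list had no camera call (adjusted p = 0.0915) and fell by fry (adjusted p = 0.0436): 4 of 11 genes fell, among them Lef1 (-1.59) and Otx2 (-1.85), and Dnmt3b rose to 562 ± 108 CPM against 302 ± 87.6 CPM. Among the other lists without a camera call were FGF and ERK targets (2 rose, 3 fell), FGF and PDGF ligands and receptors (5 rose, 4 fell), LIF and STAT3 signalling (6 rose, 4 fell), imprinted genes (5 rose, 3 fell) and DNA methylation enzymes (1 rose, 3 fell). By fry, upward calls were made for definitive and anterior endoderm (adjusted p = 0.00780), FGF and ERK targets (0.0442), FGF and PDGF ligands and receptors (0.0112), LIF and STAT3 signalling (0.0442), BMP, Nodal and TGF-beta targets (0.0331) and Wnt targets (0.0137). With library-size scaling the medians of FGF and ERK targets (0.06) and LIF and STAT3 signalling (0.18) were -0.15 and -0.03. Members of the lists without a camera call were Dusp4 (3.53), Etv5 (-1.41), Fgfr2 (2.73), Lifr (1.57), Peg3 (1.85) and Tet1, at 953 ± 48.9 CPM against 2435 ± 184 CPM. The p53 targets (1 rose, 4 fell, camera adjusted p = 0.0857, fry adjusted p = 0.0282) passed camera without double-positive replicate 2 (adjusted p = 0.0350) and without a count filter (0.0290); the member that rose, Ccng1 (0.45), was named after its value was seen and was lost without PECAM1-only replicates 1 (0.121) and 2 (0.143) and double-positive replicate 2 (0.330), with RLE (0.0874), upper-quartile (0.193) and library-size scaling (0.274), the stricter filter (0.0665) and DESeq2 (0.104). Calls were also gained by the mitochondrially encoded genes (2 rose, adjusted p = 0.345) without PECAM1-only replicate 2 (0.00865), and the ribosomal proteins (1 fell, adjusted p = 0.0857) without PECAM1-only replicate 1 (0.0139) or a count filter (0.0172). Adjusted over the list alone, the counts were the same except for neural (0 up, 5 down), mesenchymal (1 up, 0 down), Wnt targets (4 up, 3 down), epithelial junctions (4 up, 5 down), dissociation stress (5 up, 3 down), mitochondrially encoded (4 up, 0 down) and ribosomal genes (0 up, 0 down). Median and mean differed in sign for BMP, Nodal and TGF-beta targets (-0.15 and 0.47), epithelial junctions (-0.17 and 0.23) and imprinted genes (-0.08 and 0.75).

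The largest fitted rises included those of Habp2 (at least 238-fold), Cdh6 (at least 162-fold), Lpar3 (at least 155-fold), Lgals2 (at least 129-fold), Foxa2 (at least 90.7-fold), Bace2 (at least 76.9-fold) and Cubn (log2 fold change 9.75), and of Dram1, at 81.3 ± 11.7 CPM and a ratio of 1077 (counting interval 193 to 4.26e+04) to the 1 count in PECAM1-only replicate 1. The fitted falls were smaller. For genes of at least 5 CPM with the same direction in both library numbers, the largest included that of Tcea3. It had 5.03 ± 2.68 CPM against 30.5 ± 7.68 CPM (-2.60, or -3.26 without double-positive replicate 1). Others were Gm5514 (-2.55), Ndrg2 (-2.48), Nphs1 (-2.41), Nlrp14 (-2.38), Nanog (-2.36, adjusted p = 1.39e-09) and A2m (-2.34). By camera 10 lists passed, 6 up and 4 down, and 2 of them passed with an estimated correlation. The share of calls that were higher was 57.0% with TMM, 50.9% with RLE, 43.3% with upper-quartile and 39.8% with library-size scaling (the last 2 moved the median of all genes by -0.17 and -0.21), and the correction for transcript length and GC content, added after seeing the data, gave 2509 higher and 3724 lower genes.

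The remaining comparison asked what separates PDGFRa-only from double-positive cells. Transcripts of the pluripotency genes Nanog, Tdgf1 and Sox2, present in the double-positive fraction, were low in the PDGFRa-only fraction, while the naive and general pluripotency lists fell by medians of 1.45 and 0.83 and primitive endoderm regulators and receptors differed by a median log2 fold change of 0.64 (adjusted p = 0.193 for each of these 3 lists with an estimated correlation). Nanog had 0.451 ± 0.00297 CPM against 38.6 ± 2.37 CPM, Tdgf1 had 2.70 ± 1.26 CPM against 124 ± 3.83 CPM and Sox2 had 1.35 ± 0.00892 CPM against 29.9 ± 2.43 CPM (SD, n = 2). For the low levels of Nanog and Sox2, which rest on few reads, the SD understates the counting error. The endocytic receptor component Amn had 74.1 ± 12.7 CPM against 32.8 ± 1.2 CPM, and Gata4 differed by a log2 fold change of 0.72. In all, 826 genes were higher and 1624 lower, 17.6% of those tested; of those that differed at least 2-fold, 111 were higher and 1211 lower.

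Of 19 naive pluripotency genes, 12 fell and 1 rose, with 13 and 2 adjusted over the list alone. Their median was -1.45 (adjusted p = 1.14e-10, adjusted p = 0.193 with an estimated correlation); the median was -0.80 without PDGFRa-only replicate 2. Nanog fell by 6.36 on the log2 scale and Zfp42 by 1.71, and the member that rose, named after its value was seen, was Tdh (0.74; adjusted p = 0.0566 without double-positive replicate 2). Of 12 general pluripotency genes, 8 fell and none rose, with the same counts adjusted over the list alone. Their median was -0.83 (adjusted p = 1.37e-12, adjusted p = 0.193 with an estimated correlation; median -0.52 without double-positive replicate 1), with Tdgf1 at -5.59, Sox2 at -4.44 and Gdf3 at -3.17. Of 11 post-implantation epiblast genes, 6 fell and none rose, with 9 and 0 adjusted over the list alone. Their median was -1.69 (adjusted p = 1.11e-11, adjusted p = 0.193 with an estimated correlation; median -2.64 without PDGFRa-only replicate 1), with Lef1 at -5.17 and Zic2 at -3.74. Of 6 neural genes, 4 fell and none rose, with 6 and 0 adjusted over the list alone. Their median was -1.61 (adjusted p = 0.00263, adjusted p = 0.193 with an estimated correlation), with Pax6 at -2.16. The others were Sox1 (-3.32), at -4.14 without PDGFRa-only replicate 2, -3.91 without double-positive replicate 1 and -2.32 without double-positive replicate 2, and Tubb3 (-1.17; adjusted p = 0.0776 without double-positive replicate 1). Ncam1 (-1.51) was at -2.60 without PDGFRa-only replicate 1 and at -0.75 (adjusted p = 0.124) without replicate 2, and was lost without double-positive replicate 1 (0.0673). Of 8 DNA methylation enzyme genes, 3 fell and none rose, with 4 and 0 adjusted over the list alone. Their median was -0.39 (adjusted p = 0.00325, adjusted p = 0.296 with an estimated correlation): Tet1 had 320 ± 7.58 CPM against 953 ± 48.9 CPM, Dnmt3a fell by 1.05, and Tet2 fell by 0.71 (-0.60 with adjusted p = 0.0932 without double-positive replicate 1). Of 12 imprinted genes, 6 fell and none rose, with the same counts adjusted over the list alone. Their median was -0.67 (adjusted p = 0.00211, adjusted p = 0.313 with an estimated correlation, adjusted p = 0.0790 with fry), with Mest at 12.6 ± 5.08 CPM against 115 ± 26.9 CPM and Snrpn at -1.38.

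Of 14 FGF and ERK targets, 6 fell and none rose, or 6 and 1 adjusted over the list alone. Their median was -0.60 (adjusted p = 0.0154, adjusted p = 0.193 with an estimated correlation; median -0.36 without double-positive replicate 2), with Etv5 at 16.4 ± 2.23 CPM against 66.2 ± 4.92 CPM and Spred1 at -1.23. Of 11 FGF and PDGF ligands and receptors, 4 fell and 1 rose (5 and 2 adjusted over the list alone), and the list passed downwards (adjusted p = 0.0131, adjusted p = 0.296 with an estimated correlation) with a mean of -1.78 and a median of 0.08. This call was lost without PDGFRa-only replicate 1 (adjusted p = 0.0662, median -0.01) or 2 (0.245, median -0.20), without a count filter (0.274) and with the stricter filter (0.0630). Fgfr1 had 5.04 ± 1.42 CPM against 41.7 ± 0.499 CPM, Pdgfc, Fgf15 and Fgf4 also fell, and Fgfr4 (0.78) rose, named after its value was seen. Fgfr4 was lost without double-positive replicates 1 (adjusted p = 0.224) and 2 (0.0655) and with DESeq2 (0.0705), and Fgf15 without PDGFRa-only replicate 2 (0.0624) and with DESeq2 (0.0656). Of 8 Wnt targets, 3 fell and none rose, with 3 and 1 adjusted over the list alone. Their median was -0.48 (adjusted p = 0.0153, adjusted p = 0.193 with an estimated correlation), a call lost without PDGFRa-only replicate 2 (adjusted p = 0.166) or a count filter (0.268), and the median was -0.05 without double-positive replicate 1. Tcf7 was at -1.48, Lef1 at -5.17 and Axin2 at -0.84, the last lost without any 1 of PDGFRa-only replicate 2 (adjusted p = 0.206), PECAM1-only replicates 1 (0.0516) and 2 (0.0510) and double-positive replicates 1 (0.297) and 2 (0.0778) and with DESeq2 (0.193). Of 18 cell cycle genes, 7 fell and none rose, with 8 and 0 adjusted over the list alone. Their median was -0.32 (adjusted p = 0.0153, adjusted p = 0.222 with an estimated correlation; adjusted p = 0.0939 without double-positive replicate 1), with Top2a at 715 ± 126 CPM against 1264 ± 36.9 CPM. Of 12 p53 targets, 3 fell and none rose, with the same counts adjusted over the list alone. Their median was -0.25 (adjusted p = 0.0131, adjusted p = 0.193 with an estimated correlation; adjusted p = 0.0511 without double-positive replicate 2). Their median was -0.39 without PDGFRa-only replicate 2 and -0.40 without double-positive replicate 1. The 3 were Perp (-3.96), Trp53inp1 (-1.36) and Pmaip1 (-1.41, or -2.09 without PDGFRa-only replicate 2).

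Primitive endoderm regulators and receptors rose in 10 of 15 genes and fell in none, with 12 and 0 adjusted over the list alone. Their median was 0.64 (adjusted p = 7.43e-07, adjusted p = 0.193 with an estimated correlation), with Amn at 1.17 and Pth1r at 1.07. Of 17 basement membrane genes, 12 rose and 3 fell, with 13 and 3 adjusted over the list alone. Their median was 0.55 (adjusted p = 0.0385, adjusted p = 0.612 with an estimated correlation). That call was lost without double-positive replicate 1 (adjusted p = 0.274), with the stricter filter (0.0829), with library-size scaling (0.0525), with the library number as a block (0.0501), in a fit of these 2 fractions alone (0.0507) and with fry (0.290). Col4a2 rose by 1.02, and the 3 that fell were Col18a1 (-4.11), Lama5 (-1.88) and Fn1 (-1.19). Of 7 visceral endoderm genes, 2 rose, Rbp4 (1.40) and Spink3 (1.19), with the same count adjusted over the list alone. Their median was 0.59 (adjusted p = 0.00905, adjusted p = 0.193 with an estimated correlation). It was 0.19 without PDGFRa-only replicate 2 and 0.36 without double-positive replicate 1. Of 10 parietal endoderm genes, 6 rose and 1 fell, with 7 and 1 adjusted over the list alone. Their median was 0.55 (adjusted p = 0.0385, adjusted p = 0.296 with an estimated correlation). That call was lost without PDGFRa-only replicate 2 (adjusted p = 0.0725) or double-positive replicate 1 (0.141), with the stricter filter (0.0851) and with fry (0.0897). The member that fell was Vim, at 53.9 ± 0.409 CPM against 198 ± 4.65 CPM. The medians of these endoderm and basement membrane lists are close to a more general difference. Over 130 genes nearly absent from the PECAM1-only fraction, whatever their function, the double-positive level was a median of 65.3% of the PDGFRa-only level. That set can include members of these lists. The medians therefore do not show a rise particular to endoderm genes. The endothelial and blood list rose in 2 of 7 genes (3 adjusted over the list alone) without a camera call (adjusted p = 0.132, or 0.0428 without PDGFRa-only replicate 2). The 2 were Flt1 (0.59; 0.43 with adjusted p = 0.269 without double-positive replicate 1) and Runx1 (0.59), at 0.30 (adjusted p = 0.273) without PDGFRa-only replicate 1 and 0.44 (0.274) without double-positive replicate 2, and lost with library-size scaling (0.0578). The dissociation stress list rose in 1 of 14 genes (1 adjusted over the list alone), the transcription factor gene Jun, at 1.02 (0.76 without PDGFRa-only replicate 2, adjusted p = 0.0677, and 0.69 without double-positive replicate 1, adjusted p = 0.184). That list had an adjusted p of 0.177, and of 0.0261 without PDGFRa-only replicate 1 and 0.0117 without double-positive replicate 2. Median and mean differed in sign for FGF and PDGF ligands and receptors as above, LIF and STAT3 signalling (0.20 and -0.15), epithelial junctions (0.00 and -0.52) and glycolysis (0.05 and -0.12), and the mitochondrially encoded list had a median of -0.03 with a test that pointed up (adjusted p = 0.854). With library-size scaling the medians of epithelial junctions and glycolysis were -0.07 and -0.02, and with RLE that of the mitochondrially encoded list was 0.00.

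Among genes of at least 5 CPM with the same direction in both library numbers, the largest rise was of Fam219a. It had 13.4 ± 2.04 CPM against 3.69 ± 0.791 CPM (1.84, adjusted p = 0.000382). Next came Adamtsl5 (1.72), Trappc2l (1.52), Dpcr1 (1.44), Tmem256 (1.41) and Rbp4, a retinol carrier gene (1.40). Ptges2 (1.40) was lost without double-positive replicate 2, and Map1lc3a (1.39) without double-positive replicate 1. The largest fitted falls included those of genes with 0 counts in the PDGFRa-only fraction, whose bounds are lower than the fold of Nanog: Prmt8, at 10.3 ± 1.26 CPM in the double-positive fraction (at least 37.9-fold lower), Nphs1 (at least 32.1-fold), Slc27a2 (at least 22.6-fold), Pla2g1b (at least 20.3-fold), 2900026A02Rik (at least 19.1-fold) and Ngfr (at least 14.2-fold). Cobl had 38.1 ± 4.59 CPM against 1 count, in replicate 2, a ratio of 422 (counting interval 75.4 to 1.67e+04), and Fgf4 had 26.1 ± 2.89 CPM against 1 count, in replicate 1, a ratio of 289 (51.6 to 1.15e+04). By camera 15 lists passed, 4 up and 11 down, and with an estimated correlation 0 did (limma; 4 at an unadjusted p below 0.05, 13 by fry, among them BMP, Nodal and TGF-beta targets, downwards with adjusted p = 0.0218, which camera did not call). Without double-positive replicate 1 or 2 the number of genes past the threshold was 1326 or 1444, and the correction for transcript length and GC content, added after seeing the data, gave 2353 higher and 1321 lower genes.

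The position of the double-positive fraction was measured for each gene that differed between the single-positive fractions, on a log2 scale where the PECAM1-only level is 0 and the PDGFRa-only level is 1. For the 4193 genes higher in the PDGFRa-only fraction the median position was 0.75 (quartiles 0.60 to 0.85; SD over the 2 double-positive libraries 0.026), and 94.8% of them lay between 0 and 1. For the 4012 lower genes it was 0.46 (0.34 to 0.59; SD 0.013), and 97.6% lay between 0 and 1. These positions carry no test. The log2 fold changes of both PDGFRa-positive fractions over the PECAM1-only fraction correlated across 13909 genes with r = 0.888 (covariance 2.62). The same PECAM1-only libraries enter both, so 50 simulations with unchanged groups were run on 13697 genes: r was 0.876 in the data and had a median of 0.486 and a highest value of 0.519 in the simulations, with covariances of 2.01 and 0.0615. Called in both, 2971 genes were higher and 2237 lower, against 914 and 660.0 for independent calls and at most 1 in a simulation, and 1 gene went in opposite directions.

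**Figure D3:**
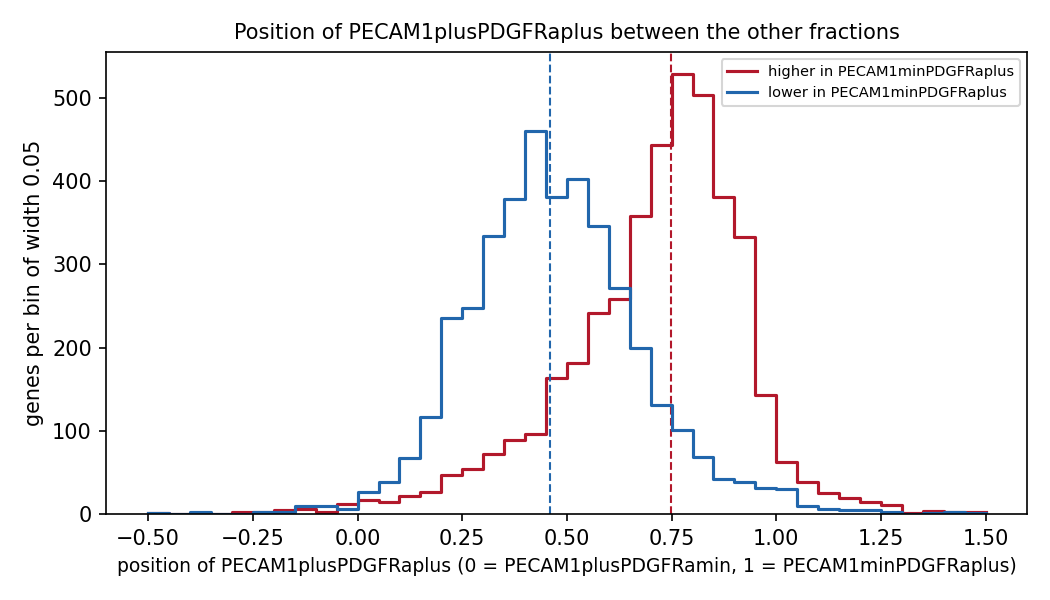
Histogram of the position of the double-positive fraction (0 is the PECAM1-only and 1 the PDGFRa-only level, log2 scale) for genes higher and genes lower in the PDGFRa-only fraction; dashed lines mark the medians. The medians lie at 0.75 and 0.46.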

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

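The tests after corrections for transcript length and GC content, and without ribosomal RNA-like genes, were chosen only after the data were seen; the rest were planned. No call of a named gene met the opposite direction in these 14 settings. No camera call of a list met the opposite direction in the settings run for lists, which left out DESeq2, limma-voom, RPKM, other thresholds and the length and GC correction. The balance of higher and lower genes did turn with the scaling and the length and GC correction, and with other scalings 11 medians changed sign, in 7 lists without a camera call in the comparison concerned. Of 312 called results of named list genes and of the genes with the largest changes, 264 were past the threshold wherever tested in the 14 settings run for single genes and 48 were not in at least 1, while 21 that had not been called gained a call in at least 1. These settings were the other scalings and filters, DESeq2, limma-voom, the block and leaving out each library; with the stricter filter 24 results of named genes were not tested. When a library is left out, the remaining library of that fraction is assumed to vary like the other groups. The count filter was rerun as well and then required its minimum in 1 library only, which let in low-count genes. Shifts in these runs therefore do not stem from the missing library alone. Against counting error alone, the spread between the 2 libraries differed by fraction. The chi-square per degree of freedom was 28.6 for PDGFRa-only, 6.11 for PECAM1-only and 5.82 for double-positive. On this measure the assumption is weakest for the PDGFRa-only fraction. Highly counted genes weigh most in it, such as RP23-81C12.3, with 7.71% and 2.47% of counts in the PDGFRa-only libraries. It therefore does not give the spread of a typical gene. The 2 libraries per fraction and 4809661 to 7273669 counts per library limit the precision, and genes below the count filter were not tested. The causes of the shifts below were not tested, except where a setting by its construction uses fewer genes, fewer libraries or a stricter threshold.

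The 5319 genes that differed between the double-positive and PECAM1-only fractions became 3220 with an absolute log2 fold change of at least 1, and ranged from 3648 to 6253 without single libraries. The 8205 genes between the PDGFRa-only and PECAM1-only fractions ranged from 6827 to 8156. The 2450 genes between the PDGFRa-only and double-positive fractions became 1264 at an adjusted p of 0.01, 1322 with an absolute log2 fold change of at least 1, 773 with limma on log2(RPKM + 1), 940 with limma on log2(RPKM + 0.1) and 4593 with the length and GC correction and the block, and ranged from 1326 to 2945 without single libraries. DESeq2 gave 7074, 4127 and 1702 genes in the same order of comparisons as the lists that follow, limma-voom 8186, 5352 and 2481. With an estimated correlation, the lists passing camera were 0 between the PDGFRa-only and PECAM1-only fractions (limma; 5 at an unadjusted p below 0.05, 15 by fry), 2 between the double-positive and PECAM1-only fractions (18 by fry) and 0 between the PDGFRa-only and double-positive fractions (4 at an unadjusted p below 0.05, 13 by fry).

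The median position of the double-positive fraction for higher genes was 0.717 with RLE scaling and ranged from 0.717 to 0.768 without single libraries. For lower genes it was 0.506 with RLE, 0.530 with upper-quartile and 0.540 with library-size scaling, 0.422 without a filter, 0.510 with the stricter filter and 0.423 for genes with an absolute log2 fold change of at least 1, and ranged from 0.394 to 0.453 without single libraries. The correlation of fold changes across genes was 0.890 with library-size scaling, 0.742 without a filter and 0.912 with the stricter filter, and ranged from 0.841 to 0.891 without single libraries. The runs without single libraries also had the looser count filter, so these ranges mix both changes.

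With the library number as a replicate block, 8397, 5644 and 2834 genes passed in the 3 comparisons. The main model without pairs was fixed before the data were examined. Deviations of same-numbered libraries from their group means correlated across genes with r of -0.03, 0.13 and 0.18. These values do not exclude that same-numbered libraries share an experiment.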

Other observations

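The gene families in this part and the members named from them, the test of how even the shares of PECAM1-only genes were, and the tests of the size of the falls after the length and GC correction were chosen only after the data were seen; the other tests were written before their results. Families were defined by symbol stem, and 37 had enough tested members. Of these, 9 passed camera between the PDGFRa-only and PECAM1-only, 12 between the double-positive and PECAM1-only and 8 between the PDGFRa-only and double-positive fractions, and 0 did with an estimated correlation (limma; 5, 5 and 2 at an unadjusted p below 0.05). The 3 families below are a choice among those that passed; the keratin genes had a smaller adjusted p between the PDGFRa-only and PECAM1-only fractions (0.000365). All 7 tested Nlrp genes, which encode pattern-recognition receptors of the NOD-like family, several of them active in oocytes and early embryos, were lower in the PDGFRa-only than in the PECAM1-only fraction (median log2 fold change -7.70, or -4.25 with the 4 genes at 0 counts set to their floor, camera adjusted p = 0.00229, adjusted p = 0.595 with an estimated correlation). All 7 were also lower in the double-positive than in the PECAM1-only fraction (median -1.81, adjusted p = 0.00601, adjusted p = 0.425 with an estimated correlation). Nlrp14 was not detected in the PDGFRa-only libraries, stood at 3.69 ± 0.348 CPM in the double-positive and at 19.3 ± 1.55 CPM in the PECAM1-only fraction (SD, n = 2). Subunits of the vacuolar proton pump, which acidifies endosomes and lysosomes, went the other way: of 16 Atp6v genes, 13 rose in the PDGFRa-only over the PECAM1-only fraction and 1 fell (median 1.16, adjusted p = 0.00608, adjusted p = 0.332 with an estimated correlation). Atp6v0a1 had 495 ± 60.4 CPM against 31.2 ± 1.35 CPM, while the member that fell, Atp6v0a4, had 1.73 ± 0.0949 CPM against 17.2 ± 1.86 CPM (SD, n = 2). Of 13 serpin genes, 8 rose and 2 fell in the same comparison (median 2.27, adjusted p = 0.00307, adjusted p = 0.294 with an estimated correlation), among them Serpinh1, the collagen chaperone of the basement membrane list, at 1203 ± 107 CPM against 15.9 ± 6.6 CPM. The medians of these 3 families kept their sign under RLE, upper-quartile and library-size scaling.

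The double-positive fraction lay between the other fractions for most genes, and this pattern might reflect RNA of the 2 other kinds of cells mixed in its libraries. Among 75 genes nearly absent from the PDGFRa-only fraction, the double-positive level was a median of 28.5% of the PECAM1-only level (quartiles 24.9% to 32.0%), and among 130 genes nearly absent from the PECAM1-only fraction it was 65.3% of the PDGFRa-only level (57.3% to 70.0%). Only 7 genes lay above both or below both other fractions, against a median of 8 and a highest value of 17 in 50 simulated mixtures, and the SD of the log2 share over the 75 genes was 0.274, against a highest simulated value of 0.346, so neither test excluded a mixture. The cells were gated on the proteins of both Pecam1 and Pdgfra. Each gene also belongs to the set it is compared with here, by the rule of at least 20 CPM in a single-positive fraction and at most 2% of that level in the other. Pecam1 stood at 32.0% of the PECAM1-only level, near the upper quartile of its 75 genes. Pdgfra stood at 96.0% of the PDGFRa-only level, above the quartiles of 57.3% to 70.0% of its 130 genes. Bulk libraries leave cells that each express both programmes at an intermediate level, doublets, mis-sorted cells and a mixed gate all open.

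Genes that differed between the PDGFRa-only and double-positive fractions also differed in transcript length and GC content: the median was 2618 bp and 53.1% for higher genes, 3956.5 bp and 48.5% for lower genes and 3174 bp and 49.3% for the rest, which may stem from a bias between libraries. After each library was corrected for its trend with both, 99.3% of the higher calls remained, above the bound of 80%. The correction also re-centred each library. The median log2 fold change of the higher calls went from 0.72 to 0.84, and the lower calls moved upwards too. Such a shift keeps higher calls whatever their cause, so this share cannot decide about the bias. Of the lower calls 79.95% remained, just under the bound of 80% set before, and 86.6% remained with the block. Over all 1616 lower calls with a known length the median log2 fold change was -1.85 before and -1.67 after the correction (quartiles -3.17 to -0.75 after), which argues against this bias as the whole cause of the falls as a set. The 324 lower calls that ended had a median of -0.71 (quartiles -0.88 to -0.58) before and -0.40 (-0.59 to -0.30) after the correction, so they ended because they shrank towards 0. These 324 were picked by that outcome, so their shrinking tests nothing. For them the bias, the re-centring and a difference between the cells cannot be told apart. A difference between the cells of the fractions themselves stays open and untested.

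A gained or lost autosome in the cells of a fraction, which long ESC culture can produce, could shift many genes together. The largest difference between the median log2 fold change of an autosome and that of all other autosomal genes, PDGFRa-only against PECAM1-only, was 0.179, on chromosome 19 (adjusted permutation p = 0.0759, 1000 permutations), below the bound of 0.4 set for a change of a whole autosome in most cells. Between the double-positive and PECAM1-only fractions, chromosomes 6, 8, 17 and 19 passed the permutation test (adjusted p = 0.0380), with differences of -0.10, -0.09, -0.09 and 0.12. The test argues against such an autosomal change in most cells of the PDGFRa-only or the PECAM1-only fraction alone. Changes in fewer cells, whose shift would stay below the bound, and changes shared by both fractions stay open. The bound covered autosomes alone. The 588 genes of the X chromosome differed from the autosomal median by -0.01 between the PDGFRa-only and PECAM1-only fractions. The 8 tested genes of the Y chromosome differed by -1.68 (permutation p = 0.00599), by -0.67 between the double-positive and PECAM1-only fractions (p = 0.0400) and by -0.99 between the PDGFRa-only and double-positive fractions (p = 0.00699), without adjustment. Between the PDGFRa-only and PECAM1-only fractions 6 of the 8, named after their values were seen, fell. They were Usp9y (-3.11), Uba1y (-4.20, or -4.83 without PDGFRa-only replicate 2), Zfy1 (adjusted p = 0.000395, log2 fold change -2.90 without that library), Kdm5d (-1.34), Uty (-0.70) and Zfy2, at 0 counts in the PDGFRa-only fraction and at least 8.37-fold lower. Uty was lost without PDGFRa-only replicate 2 (adjusted p = 0.105) and PECAM1-only replicate 1 (0.247). Ddx3y (adjusted p = 0.544) and Eif2s3y (adjusted p = 0.790) did not pass. No explanation of the Y chromosome values was tested.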
